A study of Mus musculus with 4 samples.

How the data were processed

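RNA of dissected whole cochleae from wild-type mice and littermates homozygous for the cello allele of Ikzf2, at postnatal day 8, was sequenced in 4 libraries after TruSeq preparation, per the labels. The deposited values are CPM per gene, with 1 file per library. The reads were aligned with TopHat to GRCm38, per the submitters' processing notes. The read counter, its strand setting and the annotation release are not given in the sources used here. Without a known strand setting, reads of a gene and of an overlapping or antisense partner cannot be told apart, and genes with near-identical copies, such as the haemoglobin genes, are uncertain. The authors scaled the CPM to all counted alignments, including 5 entries that name no gene, as the sums of the values show. Those entries were kept out of all tests. They held 11.7% and 9.54% of alignments outside genes in wild-type and 12.5% and 11.9% in cello, 14.0% and 14.1% against 13.0% and 14.6% of alignments that were not unique, and 3.40%, 3.53%, 3.51% and 3.45% that were ambiguous between genes.

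Each CPM was a whole multiple of the smallest value in its file for 100% of the values (tolerance 0.001 of a read), so whole reads were recovered. Of 37239 gene identifiers, 36504 matched a symbol and 36588 a position in GENCODE M21, which uses the build named by the submitters. A count of 3 reads, the upper limit that a count of 0 allows, corresponds to 0.0603, 0.0712, 0.0707 and 0.0632 CPM in the 4 libraries, and covers counting error only.

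Genes with at least 1 CPM in at least 2 of the 4 libraries were tested, 14721 in all. Values were transformed as log2(CPM + 0.5), without rescaling, and fitted by group in limma 3.58.1 (R 4.3.3) with a variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(CPM + 0.5) scale, cello minus wild-type, which understates the change of low genes. CPM are means with the SD of 2 libraries. An exact permutation test of 2 against 2 libraries cannot go below a p of 0.333 and was not used for single genes. The 25 gene lists were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry from limma beside it. The estimated correlation rests on the residuals of 4 libraries. The count tests edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 (Wald test) were run on the recovered reads as alternatives, and DESeq2 left 1142 adjusted p undefined. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

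The groups, gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Ikzf2, Car7 and Ppp1r17 are always named, as is every measured gene of the outer hair cell list. Up to 10 genes per direction past the adjusted threshold with the largest change were to be named, if their groups did not overlap. Where fewer passed, up to 5 per direction with the smallest unadjusted p took their places, named as not passing and leaving out predicted genes, Rik names and pseudogenes. From each other list up to 3 members with the smallest unadjusted p are named. Members of a list that passed when adjusted over the list alone, and Myo7a, Myo6, Pvalb, Otof, Tbx2, Fgf8, Atp2a3, Shtn1, Tectb, Ibsp, Coch and Tecta, were named after their values were seen where the rule did not reach them. A list of 20 epithelial genes and CPM recomputed over the reads in genes were chosen after seeing the data. The spread of changes within the outer hair cell list was first tested with Cochran's Q, which was replaced by a count of 95% intervals because it takes the errors of 2 against 2 libraries as known and overstates differences. A test on Otof alone, and a test of how many outer hair cell genes lay below all other epithelial genes, were run and dropped, because they rested on genes picked after their values were seen. In each of the outer hair cell and Schwann cell lists 1 member was kept in the tests of the list and is not reported here by itself. Ahsp was not analysed here and is missing from the erythroid list.

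The alternatives were pseudocounts of 0.1 and 1, no filter, a mean CPM of at least 5, TMM and median-of-ratios rescaling, quantile normalization, CPM without haemoglobin and mitochondrially encoded genes, limma without the trend and with robust moderation, the replicate number as a block, both count tests, and leaving out each library. The tests were tested on simulated data of the same 14721 genes with known changes in the cello against wild-type comparison. Of 100 genes changed 2-fold, limma recovered 66%, edgeR 67% and DESeq2 77%, and each recovered 95% of 100 genes changed 4-fold. The false calls were 15 of 176, 16 of 178 and 47 of 219. The simulated genes varied independently, without the shifts shared by many genes of a library that the real libraries show. These rates therefore need not hold for the real data. In camera with the preset correlation 1.67% of 300 unchanged lists had an unadjusted p under 0.05, and 100% of 100 lowered lists did. With an estimated correlation the shares were 0% and 100%. The simulated genes varied independently of each other, and the list calls on the real data use adjusted p.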

Results

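Whole cochleae of mice at postnatal day 8 were profiled by RNA-seq in 2 genotypes. Cello is a mutant allele of Ikzf2, the gene of helios, a zinc finger transcription factor of the Ikaros family that is expressed in outer hair cells, the electromotile sensory cells that amplify sound in the cochlea. Wild-type mice were compared with littermates homozygous for cello, with 2 libraries per genotype. The labels call these biological duplicates. They do not say whether a library came from 1 animal or from several, or that equal replicate numbers share a litter. P-values of single genes therefore measure the spread between these 4 libraries. Those of camera at the preset correlation and of Fisher's exact test take genes as units and do not measure replication between animals. The wild-type libraries held 49719984 and 42152616 counted alignments and the cello libraries 42450937 and 47463910, of which 71.0%, 72.8%, 70.9% and 70.0% lay in annotated genes. A single read was worth 0.0201 to 0.0237 CPM. The comparison asks which cochlear transcripts differ when helios is mutant, and whether those of outer hair cells do.

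Transcripts of outer hair cells, of hair cell identity genes and of the hair bundle were lower in the cello cochlea, whereas transcripts of spiral ganglion neurons and of Schwann cells were higher. The largest differences in the outer hair cell list were those of Ocm, which encodes the calcium buffer oncomodulin, and of Slc26a5, which encodes the motor protein prestin. Ocm stood at 111.8 ± 5.99 CPM in wild-type and 25.2 ± 12.3 CPM in cello (SD, n = 2), a ratio of 4.43. Slc26a5 stood at 22.9 ± 2.91 and 9.75 ± 0.0764 CPM (SD, n = 2), a ratio of 2.34. At the level of single genes, 0 of the 14721 genes tested passed an adjusted p of 0.05 in limma, so the statements on groups rest on list tests. The 5 list calls were made by camera with a preset correlation. All were lost after adjustment with an estimated correlation (camera, adjusted p from 0.531 to 0.664) and with fry. Before adjustment, camera with an estimated correlation gave p = 0.047 for the outer hair cell list and 0.021 for the hair bundle list. Fry gave unadjusted p = 0.0059 and 0.0060 for these 2 lists. General epithelial genes, a list chosen after the data were seen, were lower to a similar degree (median log2 fold change -0.40), and the nerve difference went with a gap of similar size within wild-type.

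The mutated gene itself was measured in every library. Ikzf2 (ENSMUSG00000025997, chromosome 1, 69531214 to 69687245 of GRCm38, minus strand, protein coding) stood at 22.9 and 18.5 CPM in wild-type and at 17.7 and 16.9 CPM in cello. Its log2 fold change was -0.24 (SE 0.13), and limma gave an unadjusted p of 0.13, so no difference in its transcript level was detected. Cello is a point mutation that changes the protein, and the level of the transcript therefore does not check the genotype labels. Of the other Ikaros family genes, Ikzf5 differed by 0.09 and Ikzf1 by 0.36 on the log2 scale, and neither passed.

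The outer hair cell list, written down from general knowledge, fell as a group. Its members Slc26a5 and Ocm are also remembered as reported by the study from these samples, and the list was not tested without them. Of its 12 measured genes, 11 had lower values in cello, with a median log2 fold change of -0.33, and camera gave an adjusted p of 4.8e-06. With an estimated correlation between genes the camera adjusted p was 0.589 (unadjusted p = 0.047). By limma, 0 members passed over all genes tested, while 8 were lower and 1 was higher when adjusted over the list alone. Lmod3, an actin nucleator of the leiomodin family, stood at 28.5 ± 2.04 CPM in wild-type and 12.4 ± 0.214 CPM in cello (SD, n = 2), with a log2 fold change of -1.16 (SE 0.10). The log2 fold changes of Slc26a5 and Ocm were -1.18 (SE 0.13) and -2.21 (SE 0.32), and both were lower in each cello library than in each wild-type library. Smaller differences were found for Chrna10, a subunit of the nicotinic receptor that receives efferent input (-0.53), the aquaporin gene Aqp11 (-0.48), Lbh (-0.34), Strip2 (-0.29) and Sri, which encodes sorcin (-0.20). Dnm3, a dynamin gene also expressed in neurons, was the member with a higher value (0.55). Chrna9, a further nicotinic receptor subunit gene, stood at -0.22 and the potassium channel gene Kcnn2 at -0.02, and neither passed.

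Ppp1r17 and Car7 were named individually and kept out of the list, because the study is remembered to have reported them from these samples. Ppp1r17, a phosphatase inhibitor gene (chromosome 6, 56017497 to 56032689, plus strand), stood at 9.77 ± 0.614 CPM in wild-type and 3.36 ± 0.490 CPM in cello (SD, n = 2). Its log2 fold change was -1.42 (SE 0.17). Car7, a carbonic anhydrase gene (chromosome 8, 104534689 to 104550343, plus strand), stood at 12.8 ± 1.38 and 6.21 ± 0.977 CPM (SD, n = 2), with a log2 fold change of -0.99 (SE 0.17). Neither passed over all genes in limma (adjusted p = 0.419 for each), and DESeq2 gave adjusted p = 1.0e-05 and 0.0069. Slc26a5 and Ocm are also remembered as reported by the study. The values of these 4 genes are not independent evidence, and the camera p of the outer hair cell list includes Slc26a5 and Ocm. Slc26a5 lies on chromosome 5 from 21810655 to 21865604 (minus strand), Ocm on chromosome 5 from 144019804 to 144026670 (minus strand) and Lmod3 on chromosome 6 from 97238534 to 97252759 (minus strand).

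**Figure D1:**
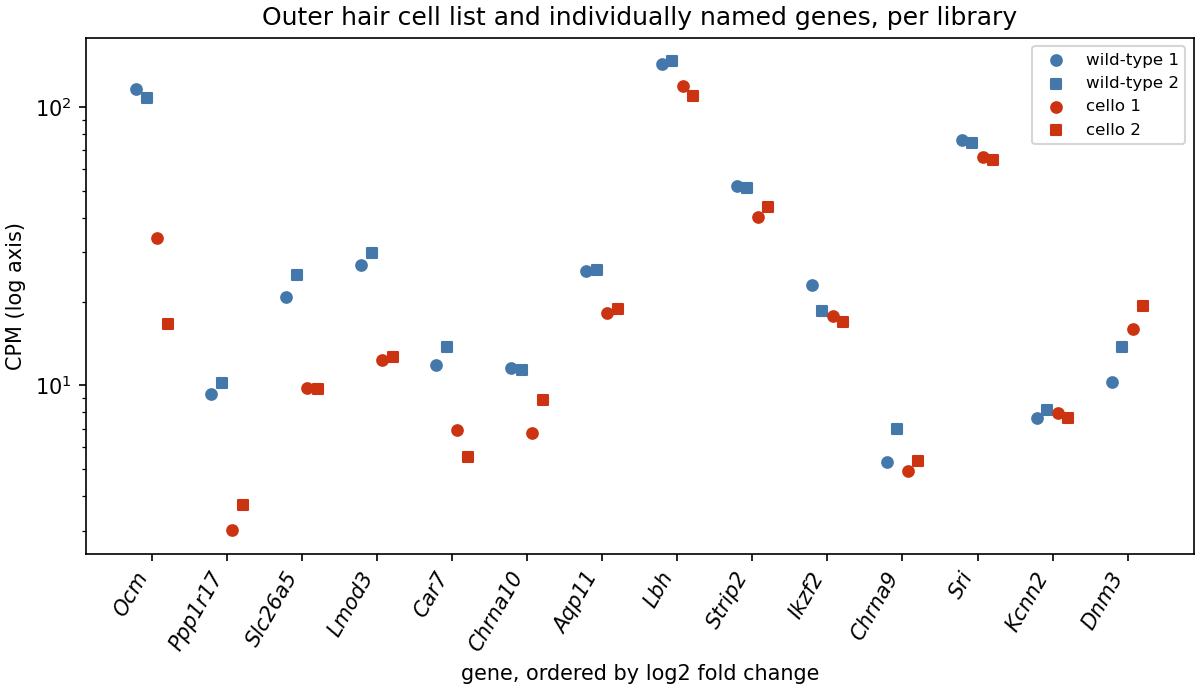
CPM on a log axis of 11 of the 12 measured outer hair cell genes and of Ikzf2, Car7 and Ppp1r17, with 1 point per library (circles for replicate 1, squares for replicate 2, blue for wild-type, red for cello), ordered by log2 fold change. Ocm stands at 116 and 107.5 CPM in wild-type and at 33.9 and 16.6 CPM in cello, while Kcnn2 lies between 7.62 and 8.16 CPM in all 4 libraries.

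Some of the genes that hair cells of both kinds use were also lower. The hair cell identity list fell, with a median log2 fold change of -0.49 over 12 measured genes (camera, adjusted p = 0.0017). Its camera adjusted p was 0.664 with an estimated correlation, and its median was -0.29 without cello replicate 1. Adjusted over the list alone 5 of its members were lower and 0 over all genes tested by limma. These were the transcription factor genes Pou4f3 (-0.86, SE 0.10), Gfi1 (-0.79, SE 0.18) and Lhx3 (-0.75), with Rasd2 (-0.99) and Smpx (-0.47). The general hair cell markers Myo7a (0.04, SE 0.20) and Myo6 (-0.06, SE 0.08) did not pass, nor did Pvalb, which stood above 0 (0.88). The hair bundle and mechanotransduction list fell, with 27 of 29 measured genes below 0 and a median of -0.37 (camera, adjusted p = 2.1e-09). For this list camera gave an adjusted p of 0.531 with an estimated correlation (unadjusted p = 0.021). Adjusted over the list alone 4 of its members were lower, and 0 over all genes tested by limma. Strc encodes stereocilin, which links the stereocilia of outer hair cells, and stood at 17.4 ± 0.697 CPM in wild-type and 7.14 ± 1.03 CPM in cello (SD, n = 2). Tmc1, a subunit of the mechanotransduction channel, had a log2 fold change of -0.80 (SE 0.11), its partner Cib2 one of -0.55 (SE 0.12), and Ptprq one of -0.39.

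The inner hair cell list did not move as a group (median -0.05, camera, adjusted p = 0.744, with a mean of 0.13 and the test leaning up). Of its 8 members, 0 passed when adjusted over the list alone. Otof, which encodes the synaptic protein otoferlin, stood at 65.9 and 62.1 CPM in wild-type and at 67.1 and 63.4 CPM in cello, with a 95% interval of its log2 fold change from -0.18 to 0.23. Slc17a8, the vesicular glutamate transporter gene of inner hair cells, stood at -0.38, while Slc7a14 (0.48) and Calb2 (1.24), both also expressed by spiral ganglion neurons, stood above 0.

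The lists of supporting cell and stria vascularis genes moved in the same direction as the outer hair cell list. The supporting cell list fell slightly (median -0.26 over 21 genes, camera, adjusted p = 0.014), as did the stria vascularis list (median -0.24 over 16 genes, camera, adjusted p = 0.014). With an estimated correlation the camera adjusted p was 0.664 for each. By limma 0 members of either list passed over all genes tested. Adjusted over the list alone, Otog, which encodes the tectorial membrane protein otogelin, was lower in the supporting cell list (-0.61, SE 0.09), while Lfng (-0.46) and Bace2 (-0.26) did not pass. In the stria list 3 members were lower, namely Kcne1, a potassium channel subunit gene (-0.42), Esrrb (-0.38) and the pigment enzyme gene Tyr (-0.56). A list of 20 general epithelial genes, chosen after the data were seen, had 19 of 19 measured members below 0 and a median of -0.40, which is beside the median of -0.33 in outer hair cell genes and of -0.37 in hair bundle genes. The supporting cell call was lost without wild-type replicate 2 (camera, adjusted p = 0.219) and without cello replicate 1 (median -0.15, adjusted p = 0.175), and the stria call without wild-type replicate 2 (adjusted p = 0.069), with adjusted p up to 0.664 over all settings for both lists.

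**Figure D2:**
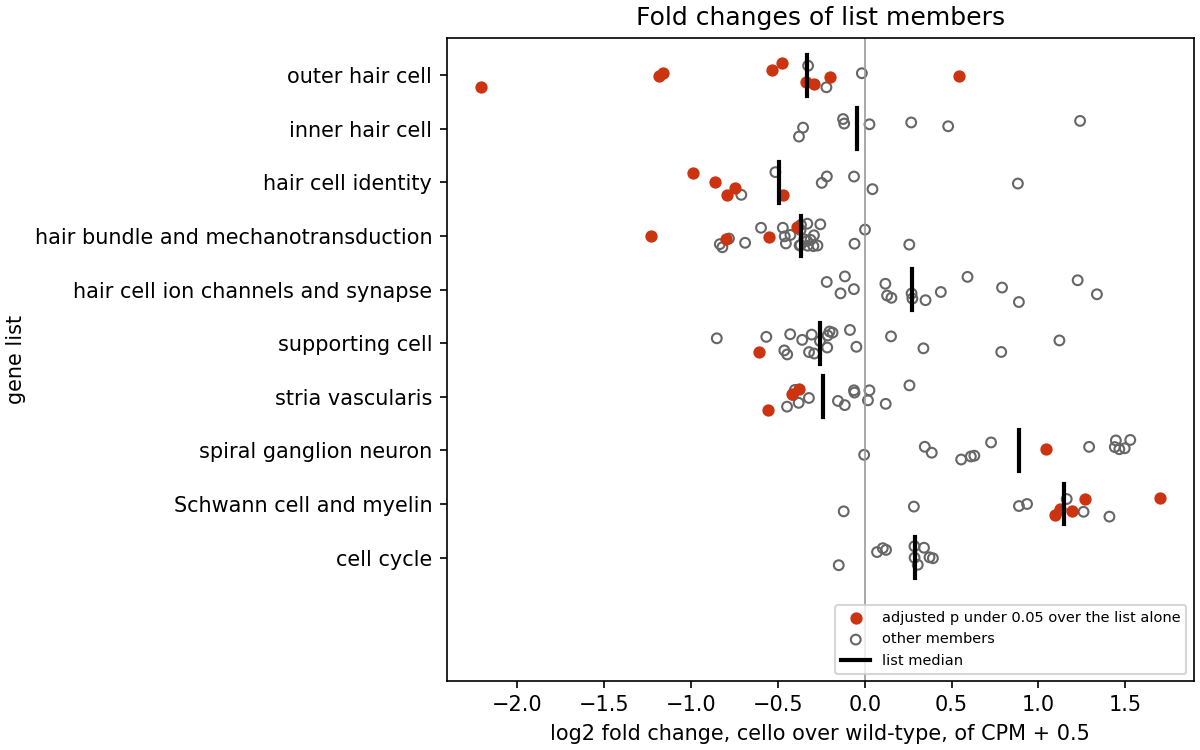
Log2 fold change of each measured member (horizontal axis) for 10 gene lists (vertical axis), with list medians as black bars and members that passed when adjusted over the list alone in red. The outer hair cell median lies at -0.33 and the Schwann cell and myelin median at 1.14.

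Neuronal and glial transcripts of the auditory nerve were higher in cello. The spiral ganglion neuron list rose, with a median log2 fold change of 0.89 over 14 measured genes (camera, adjusted p = 5.8e-08). The Schwann cell and myelin list rose, with a median of 1.14 over 12 genes (camera, adjusted p = 1.4e-07). With an estimated correlation the camera adjusted p was 0.664 for each. By limma 0 members passed over all genes tested. Adjusted over the list alone, Lypd1 was higher among the neuronal genes (1.04, SE 0.20), and 5 myelin genes were higher, among them Pmp22, a protein gene of peripheral myelin (1.27), the transcription factor gene Egr2 (1.19), Drp2 (1.13) and Ncmap (1.09). Elavl4 (1.53) and Runx1 (0.61) did not pass. This difference went with a large gap within wild-type, where the median level of the Schwann cell and myelin list, relative to the mean of the libraries on the log2 scale, was -1.04 in replicate 1 and 0.04 in replicate 2, against 0.55 and 0.69 in cello. The median over both lists was 1.11, and it was 0.54 without wild-type replicate 1 and 1.59 without wild-type replicate 2.

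The list of hair cell ion channels and synaptic genes rose, with a median of 0.27 over 16 genes (camera, adjusted p = 0.0024). Camera gave an adjusted p of 0.664 for it with an estimated correlation, and its median was 0.17 without wild-type replicate 1 and 0.56 without cello replicate 1. By limma 0 of its members passed, both over all genes tested and when adjusted over the list alone. Its members with the smallest p were Cabp1 (1.34), the active zone gene Bsn (0.79) and the sodium channel gene Scn8a (0.89), which neurons also express. The cell cycle list rose slightly (median 0.29 over 10 genes, camera, adjusted p = 0.037). With an estimated correlation its camera adjusted p was 0.822, and 0 members passed either way. The cell cycle call was lost under 13 of 19 other settings, among them without wild-type replicate 1 (median 0.00, camera, adjusted p = 0.553). Cdk1 stood at 0.29, Bub1 at 0.31 and Top2a at 0.37.

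The remaining lists did not pass in camera. Skeletal muscle genes had a median of -1.14 over 4 measured genes (adjusted p = 0.062), which was -2.02 without wild-type replicate 1 (adjusted p = 1.1e-05) and -0.22 without wild-type replicate 2, with Myl1 lower when adjusted over the list alone (-2.03) and Tnnt3 (-0.78) not passing. Among 4 measured central glia genes (median -0.71, camera, adjusted p = 0.272, with a median of -1.23 without wild-type replicate 1, adjusted p = 0.0062, and of -0.18 without wild-type replicate 2), Mobp (-1.57) and Aqp4 (-0.52) were lower and Slc1a2 was higher (0.44) when adjusted over the list alone. Of the p53 target genes (median -0.05, mean 0.03, camera, adjusted p = 0.960) Phlda3 was higher when adjusted over the list alone (0.57), while Sesn2 (-0.21) and Bbc3 (-0.22) were not past the threshold. By limma 0 members of these lists passed over all genes tested. The medians and camera adjusted p were 0.01 and 0.960 for fibrocyte genes, 0.16 and 0.134 for bone, 0.08 and 0.960 for cartilage, 0.08 and 0.272 for erythroid genes, and -0.11 and 0.963 for neutrophil and marrow genes. They were -0.01 and 0.960 for macrophage genes, 0.20 and 0.147 for endothelial genes, 0.02 and 0.963 for immediate early and heat shock genes, and 0.03 and 0.920 for interferon response genes. They were -0.01 and 0.963 for the Ikaros family, 0.07 and 0.186 for mitochondrially encoded genes and -0.70 and 0.657 for sex-linked genes. The test leaned up while the median lay below 0 for neutrophil and marrow (mean -0.09), macrophage (mean 0.05), p53 target and Ikaros family genes (mean 0.02), and it leaned down for immediate early genes while their mean was 0.06. Without cello replicate 1 the bone list was lower (median -0.58, camera, adjusted p = 4.2e-05), as was the neutrophil and marrow list (-1.51, adjusted p = 2.7e-04), and the sex-linked list was higher (0.52, adjusted p = 0.0061), whereas without cello replicate 2 the bone list was higher (1.14, adjusted p = 3.4e-11), as was the neutrophil and marrow list (1.18, adjusted p = 3.8e-04), and the sex-linked list was lower (-2.05, adjusted p = 5.0e-04). Bone genes were also higher in edgeR (camera, adjusted p = 0.041). Members of these lists with the smallest p, none of them passing, included Cldn11 (-0.42), Tbx18 (0.21) and Otos (0.62) for fibrocytes, Sox9 (-0.28), Hapln1 (1.40) and Matn1 (-0.85) for cartilage, and Jun (-0.30), Fosb (-0.49) and Dnajb1 (-0.14) for immediate early and heat shock genes.

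The make-up of the libraries differed within genotypes as well. The bone gene Ibsp stood at 1044 CPM in cello replicate 1 and 204 CPM in cello replicate 2, and at 435 and 467 CPM in wild-type. The median level of the bone list in cello replicate 1 was 1.03 above the mean of the libraries on the log2 scale, and in cello replicate 2 it was -0.72. The fibrocyte gene Coch stood at 1162 and 215 CPM in the cello libraries and the tectorial membrane gene Tecta at 35.0 and 251 CPM. The outer hair cell list stood at 0.20 and 0.22 in wild-type and at -0.24 and -0.10 in cello on that scale, and the epithelial list likewise at 0.17 and 0.25 against -0.22 and -0.16.

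**Figure D3:**
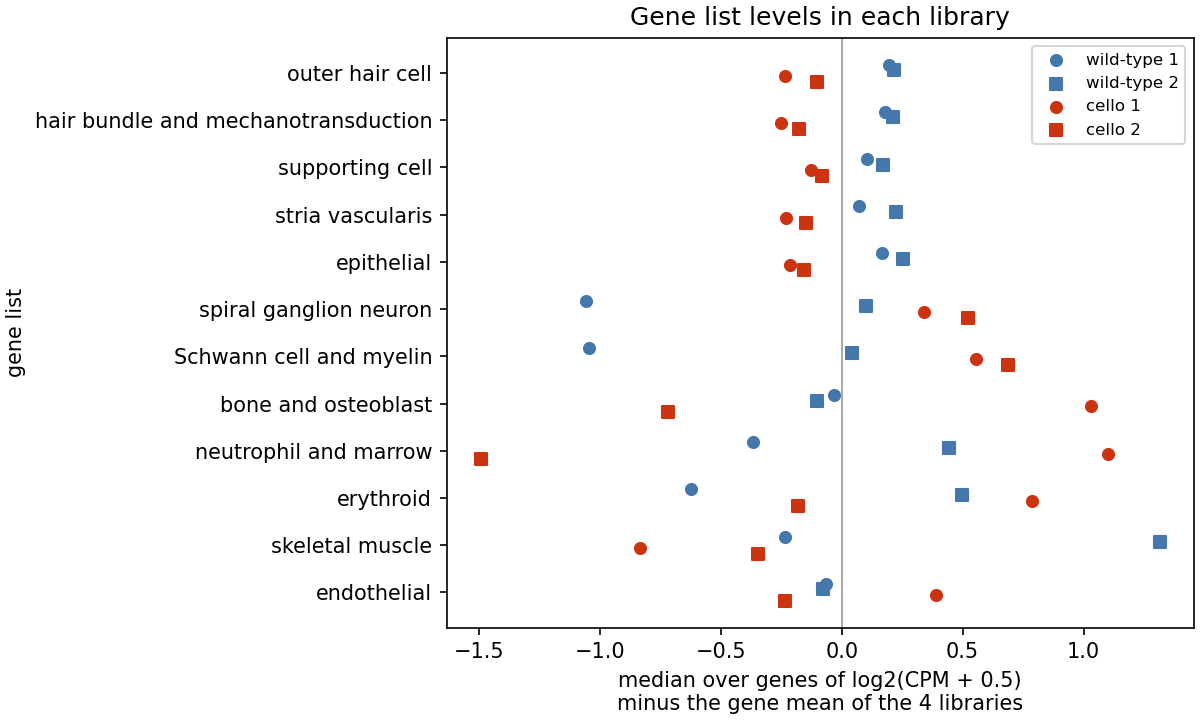
Level of 12 gene lists (vertical axis) in each library, as the median over genes of log2(CPM + 0.5) minus the mean of that gene over the 4 libraries (horizontal axis, log2). The Schwann cell and myelin list lies at -1.04 in wild-type replicate 1 and at 0.04 in wild-type replicate 2, and the neutrophil and marrow list at 1.10 and -1.49 in the cello libraries.

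Over all genes, the smallest unadjusted p among genes with lower values belonged to Wdfy1, a gene of endosomal signalling on chromosome 1 (79702262 to 79776143), which stood at 57.3 ± 2.46 CPM in wild-type and 25.6 ± 2.26 CPM in cello (SD, n = 2), followed by Lmod3, Slc26a5, Pou4f3 and Strc. Among genes with higher values the smallest belonged to the noncoding RNA genes Gas5 and Miat, to Snhg11, a host gene of small nucleolar RNAs that the annotation lists as protein coding, to Gnai1, which encodes an inhibitory G protein subunit, and to Nfasc, a cell adhesion gene of nodes of Ranvier. Gas5, the host gene of small nucleolar RNAs on chromosome 1 (161034422 to 161038539), stood at 35.7 ± 0.0595 and 68.4 ± 4.56 CPM (SD, n = 2), Miat at 29.6 ± 1.66 and 60.7 ± 5.60 CPM (SD, n = 2), and Snhg11 at 42.7 ± 12.7 and 152 ± 10.1 CPM (SD, n = 2). The log2 fold changes of Gnai1 and Nfasc were 0.61 (SE 0.08) and 0.56 (SE 0.08). None of these 10 genes passed over all genes in limma, where the smallest adjusted p was 0.419. At an unadjusted p under 0.05 limma found 651 genes higher and 952 lower, so that 40.6% were higher, and after TMM rescaling 56.5% were higher. The 0 genes called by limma and by edgeR (812 higher and 651 lower at an unadjusted p under 0.05) stood against 115 higher and 80 lower in DESeq2, all of them genes whose wild-type and cello libraries did not overlap, as was the case for 45.6% of all genes tested, where chance gives 33.3%. Without wild-type replicate 2 limma called 90 genes higher and 0 lower (817 and 228 at an unadjusted p under 0.05).

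Small p-values were spread unevenly over the chromosomes, a count made after the data were seen. On chromosome 1, which carries Ikzf2, 42 of 886 tested genes (4.74%) had an unadjusted p under 0.01 in limma, against 2.22% of genes on other chromosomes (Fisher's exact test, two-sided, adjusted over 20 chromosomes, p = 3.5e-04), and 22 of the 42 were higher and 20 lower. Wdfy1, Gas5, Nfasc, Lypd1, Phlda3 and Myl1 were among them. None of the 42 passed over all genes. No other chromosome passed.

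**Figure D4:**
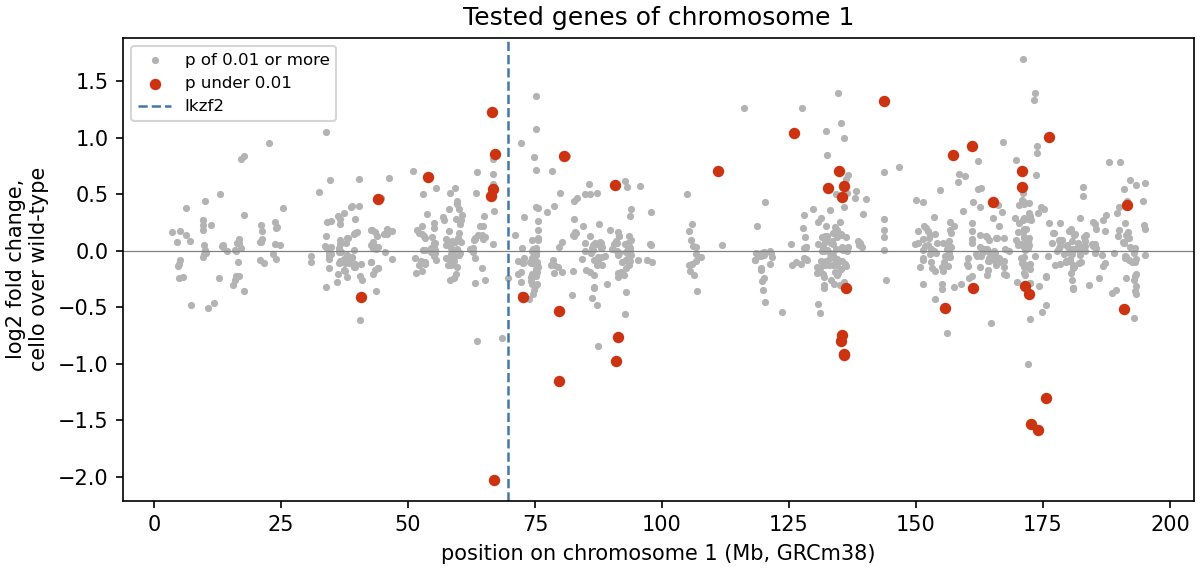
Log2 fold change of the 886 tested genes of chromosome 1 (vertical axis, cello over wild-type) by position (horizontal axis, Mb of GRCm38), with the 42 genes of limma p under 0.01 in red, other genes in grey and the position of Ikzf2 as a dashed line. The red genes lie on both sides of 0, from -2.03 for Myl1 to 1.32 for B3galt2.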

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

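Alignments outside annotated genes were not part of any comparison in the tests above. They made up 12.2% ± 0.407 of counted alignments in cello and 10.6% ± 1.496 in wild-type (SD, n = 2). The share was 12.5% and 11.9% in the cello libraries against 11.7% and 9.54% in the wild-type libraries, so that both cello libraries lay above both wild-type libraries. The gap between the wild-type libraries was larger than the difference between the means, and no test was made.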

How the results depend on the processing

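The outer hair cell list kept its direction and side of the threshold in camera under 18 settings, with adjusted p from 5.3e-11 to 9.1e-05 (2.6e-06 to 9.1e-05 when a library was left out). It lost its call in camera with an estimated correlation (adjusted p = 0.589) and with fry (adjusted p = 0.075). By either, 0 of the gene list tests passed, against 9 of 25 with camera at the preset correlation. The estimated correlation was 0.034 for the outer hair cell list and 0.0067 for the hair bundle list, against the preset 0.01. The other lists called at the preset had higher estimates, among them 0.894 for Schwann cell and myelin and 0.444 for spiral ganglion neuron genes. The hair bundle estimate lies below the preset, so a higher correlation between genes cannot account for the loss in that list. With an estimated correlation, camera bases p on the residual degrees of freedom of the 4 libraries, not on the number of genes. That alone raises p at the same difference. Further causes of the loss were not tested. Between 8 (without wild-type replicate 2) and 15 lists passed (without cello replicate 2). Skeletal muscle genes, not passing in the main test, passed under 11 settings, all lower, and not under 8, among them without wild-type replicate 2 (adjusted p = 0.294), cello replicate 1 (0.157) or cello replicate 2 (0.211). Central glia genes passed, lower, with no filter (0.042), in DESeq2 (0.044) and without wild-type replicate 1 (0.0062), and mitochondrially encoded genes, higher, in DESeq2 (0.037). With a mean CPM of at least 5 the cell cycle, skeletal muscle, central glia, neutrophil and marrow, and Ikaros family lists had too few genes left to test. The counts of genes higher in cello and genes lower in cello were 0 under all settings but DESeq2 (115 and 80) and leaving out a library (0 to 90 higher, 0 lower, the 90 without wild-type replicate 2), where the lone library is assumed to vary like the other group. The cause was not tested. DESeq2 also made the most false calls on simulated data (47), where genes varied independently of each other. With the replicate block limma called 0 genes (1001 higher and 901 lower at an unadjusted p under 0.05, by limma without it 651 and 952, by edgeR 812 and 651), and among the list calls it changed only those of the cell cycle (adjusted p = 0.078) and skeletal muscle (adjusted p = 0.014), and turned neutrophil and marrow and immediate early and heat shock genes, which did not pass (adjusted p = 0.968 each). The labels do not say that numbers pair libraries, and the correlation over genes of the within-genotype differences was 0.13. CPM over the reads in genes was chosen after seeing the data and called 0 genes (798 higher and 715 lower at an unadjusted p under 0.05). TMM factors moved the median of all genes from -0.03 to 0.01. Depth limits genes near 0.0712 CPM, the highest floor.

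Of 91 named genes, 25 passed in DESeq2 and 6 without wild-type replicate 2. Kcnn2, near 0, turned to 0.022 with TMM, 0.020 with median-of-ratios, 0.023 in edgeR, 0.021 in DESeq2, 0.014 without haemoglobin and mitochondrially encoded genes and 0.011 over reads in genes. Ngp turned to 0.073 (edgeR) and 0.078 (DESeq2) and Mpo to 0.17 and 0.18. When a library was left out the log2 fold changes ranged from -0.10 to 1.17 for Ptprc, -0.14 to 1.37 for Otos, -0.092 to 0.73 for Flt1, -0.17 to 1.35 for Car1, -2.46 to 0.43 for Uty, -0.24 to 1.17 for Phex, -0.12 to 0.60 for Pecam1, -2.13 to 0.52 for Kdm5d, -0.25 to 0.97 for Ikzf1, -2.05 to 0.64 for Eif2s3y, -0.72 to 0.20 for Camp, -0.29 to 0.79 for Hbb-bs, -1.71 to 0.85 for Ngp, -1.51 to 0.94 for Mpo and -0.063 to 0.030 for Kcnn2. None of these genes passed in limma with all libraries, and the cause was not tested.

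Several lists that did not pass in the main test gained a call or turned direction when the processing changed. Erythroid genes passed, higher, without wild-type replicate 2 (8.5e-06) and without cello replicate 2 (0.0040), endothelial genes, higher, without cello replicate 2 (2.4e-06), and immediate early and heat shock genes, lower, without cello replicate 1 (0.049) and, higher, without cello replicate 2 (0.048). Fry turned fibrocyte, cartilage, neutrophil and marrow, macrophage and Ikaros family genes (adjusted p = 0.948 each), and no filter turned fibrocyte, cartilage, macrophage and neutrophil and marrow genes (0.945 each). TMM turned cartilage (0.931) and neutrophil and marrow genes (0.899), as did median-of-ratios (0.929 and 0.891) and CPM without haemoglobin and mitochondrially encoded genes (0.984 and 0.917). Neutrophil and marrow genes also turned with a pseudocount of 0.1 (0.947), quantile normalization (0.932) and CPM over the reads in genes (0.897), interferon response genes with quantile normalization (0.932), immediate early and heat shock genes with a mean CPM of at least 5 (0.809), and they and fibrocyte genes in DESeq2 (0.959 each). When a library was left out the adjusted p of lists that turned ranged from 0.243 to 0.742 for inner hair cell, 0.206 to 0.801 for fibrocyte, 3.4e-11 to 0.294 for bone, 0.243 to 0.840 for cartilage, 8.5e-06 to 0.513 for erythroid, 2.7e-04 to 0.558 for neutrophil and marrow, 0.347 to 0.742 for macrophage, 2.4e-06 to 0.294 for endothelial, 0.048 to 0.658 for immediate early and heat shock, 0.329 to 0.851 for p53 target, 0.376 to 0.953 for interferon response, 0.329 to 0.562 for Ikaros family and 5.0e-04 to 0.553 for sex-linked genes.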

Other observations

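The tests on the epithelial list, noncoding RNAs, inner hair cell genes, the spread among outer hair cell genes, the comparison without the epithelial list, nerve tissue, the share of chromosome 1 and the splits of the libraries were chosen only after the result was seen.

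Long noncoding RNAs with a small p lay on 1 side. Of 650 measured, 12 had a limma p under 0.01, with 12 higher and 0 lower in cello, against 117 higher and 214 lower among 13813 protein coding genes (Fisher's exact test, two-sided, p = 5.7e-06). The spiral ganglion neuron and Schwann cell lists were higher in the same libraries (medians 0.89 and 1.14). Whether the noncoding RNAs rose with nerve tissue was not tested. The noncoding pattern was seen before its test, so that the Fisher p does not test it. At an unadjusted limma p under 0.05, 40.6% of genes were higher without rescaling and 56.5% after TMM. The count of noncoding and protein coding genes was not repeated after rescaling. Besides Gas5 and Miat, Meg3, an imprinted gene picked after its values were seen, stood at 1.85 and 2.54 CPM in wild-type and 6.15 and 6.19 CPM in cello. General epithelial genes were lower in 19 of 19 measured (camera in limma, adjusted p = 6.0e-11 over 26 lists, and 0.421 with an estimated correlation), but the list was chosen after the data were seen, so that these p do not test it. Epcam stood at 285 and 293 CPM in wild-type and 199.0 and 220.0 CPM in cello, Esrp1 at 55.5 and 56.9 against 42.4 and 44.0 CPM, and Elf3 at 12.6 and 12.2 against 8.06 and 5.92 CPM. These 3 were also picked after their values were seen, and 0 epithelial or noncoding genes passed over all genes in limma, against 651 higher and 952 lower at an unadjusted p under 0.05 among all genes, 0 in edgeR and 195 in DESeq2.

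Transcripts of outer hair cells and of the hair bundle were lower in cello. A smaller share of cochlear epithelium in the cello libraries remains a candidate explanation for the outer hair cell list. Camera in limma against 56 supporting cell, stria and epithelial genes gave adjusted p = 0.394 (over 4 lists, with 0.872 for hair cell identity and 0.031, higher, for inner hair cells). These 56 included the 19 measured epithelial genes, chosen after the data were seen and all lower in cello. Including them moved the median of the reference genes from -0.26 to -0.33, which favours finding no difference for lists that fell. The stria genes include the pigment enzyme gene Tyr, so the reference genes do not mark epithelium alone. Without the epithelial genes, against 37 genes, the adjusted p was 0.134 for the outer hair cell list and 0.377 for hair cell identity, and inner hair cells no longer passed (adjusted p = 0.134). For the hair bundle list that explanation cannot be told apart from a change of its own. In camera the adjusted p was 0.394 against the 56 genes, a value weakened by the choice of the epithelial genes. Against the 37 the unadjusted p was 0.019 and the adjusted p 0.077. Ocm, Slc26a5 and Lmod3 lay below all 56 of those genes, the lowest being Tectb at -0.85, which stood at 748 and 2633 CPM in the cello libraries, but these 3 are the lowest members of their list, and their place excludes nothing. Fewer hair cells of both kinds cannot be told apart from a change in outer hair cells, since 4 of the 8 inner hair cell genes had a 95% interval that reached the outer hair cell median of -0.33 (Slc17a8, Tbx2, Fgf8 and Atp2a3) and 4 did not (Otof, Slc7a14, Calb2 and Shtn1). Fewer outer hair cells cannot be told apart from less transcript per cell, since 4 of the 12 genes had a 95% interval that excluded the list median (Ocm, Slc26a5 and Lmod3 below it, Dnm3 above) but some members have other sources in the cochlea. An effect of mutant helios on these genes stays open and untested.

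Transcripts of neurons and myelin were higher in cello, and a varying amount of nerve tissue between libraries may account for it. Over the 26 genes of both lists the median gap between the wild-type libraries was 1.15 on the log2 scale, against 0.25 between the cello libraries and a median difference of 1.11 between genotypes, a ratio of 1.04. Without wild-type replicate 1 the difference was 0.54 and without wild-type replicate 2 it was 1.59. A biological difference between the genotypes stays open and untested.

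Chromosome 1 held more genes with a limma p under 0.01 than an even spread over chromosomes gives (adjusted p = 3.5e-04, Fisher's exact test). Nerve tissue genes that happen to lie there are argued against as the whole cause. The excess held among genes lower in cello (20 of 401, or 4.99%, against 2.49% elsewhere, Fisher's exact test, two-sided, p = 0.0055). That count speaks to nerve tissue only, and the test takes neighbouring genes as independent. The 20 lower genes included the epithelial gene Elf3 and the skeletal muscle gene Myl1. A differing share of other tissues therefore stays open and was not tested. Neighbours of Ikzf2, carried along with the mutant allele from another strain, could give such an excess, but the share within 20 Mb of Ikzf2 (10 of 218) was close to that on the rest of the chromosome (32 of 668, Fisher's exact test, p = 1, odds ratio 0.96, 95% interval 0.41 to 2.03). Whether such neighbours add to the excess stays open, since the interval is wide and the length of any inherited segment is not known. By 25 Mb bins the share was highest from 125 to 150 Mb (11 of 119) and from 150 to 175 Mb (11 of 183).

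The 4 libraries can be split into 2 pairs in only 3 ways, too few for a share under 0.05. The genotype split gave 1603 genes with a limma p under 0.05. The highest of the other splits, replicate 1 of both genotypes against replicate 2 of both, gave 406, and the remaining split gave 178. Of the 3 splits, only the genotype split itself reached 1603 genes.

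Ifi202b on chromosome 1 (173962568 to 173982744), picked after its values were seen, stood at 1.97 and 1.99 CPM in wild-type and 0.283 and 0.379 CPM in cello. Xist stood at 372 and 286 CPM in wild-type and 827 and 163 CPM in cello. The Y-linked gene Ddx3y stood at 56.2 and 56.2 against 13.8 and 95.1 CPM. Each library thus held transcripts of both, which argues against libraries of 1 animal, and the balance of the 2 genes differed between the cello libraries. Rps2, a ribosomal protein gene with many processed copies in the genome, stood at 1.83 and 35.8 CPM in wild-type and 1.51 and 57.0 CPM in cello, and Rps18 at 4.41 and 11.7 against 4.78 and 20.7 CPM, with the lower value in replicate 1 of either genotype. Over 9976 genes with a mean of at least 10 CPM, 113 differed by more than 2-fold between the cello libraries and 115 between the wild-type libraries, while the correlation of log2 values over all genes tested was 0.982 within cello, 0.989 within wild-type and 0.988 between wild-type replicate 2 and cello replicate 2.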
